A study of Homo sapiens with 10 samples.

How the data were processed

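Small RNA of exosomes was measured on 10 Agilent human miRNA arrays, 1 per sample and in 1 colour (Cy3). The groups were taken from the sample titles: 3 controls that received buffer, and macrophages inoculated with Treponema pallidum (TP) whose exosomes were collected after 12 h (2 samples), 24 h (2 samples) or 48 h (3 samples). The control titles give no collection time. The labels do not say whether samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The labels' extraction and labelling text describes a kit for whole blood, removal of globin message and labelled cRNA, which is not how a miRNA array of cell-line exosomes is usually prepared, so how this RNA was isolated and labelled stays unknown.

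The deposited scanner files hold intensity values per spot that Agilent Feature Extraction 12.0.3.1 had background-subtracted and spatially detrended, per the file headers. Version 9.1 is named in the submitters' processing notes. A spot counted as well above background when its signal passed 13 standard deviations of the background, per the file headers. The deposited flag columns, of the unit class "other", mark well-above-background, saturated and outlier spots and miRNAs detected by the software. The deposited value table of the series holds log2 values for which no scaling method is given in the sources used here. Its column medians lay between 1.76 and 1.84, and each column correlated with the log2 total gene signal of its own array (r between 0.847 and 0.985 across detected miRNAs, which are not independent replicates, with slopes of 0.96 to 1.69). That table was used as an alternative only, and its scaling and centring stay unknown.

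Each array carries 50980 spots of 5893 probes for 2549 miRNAs, and 2164 control spots were left out. Outlier spots were left out, and no spot was saturated. Each array's processed signal was divided by its 75th percentile over the 32 probes detected on all 10 arrays (the reference signal), set to at least the smallest positive scaled value (3.39e-09) and taken as log2. Spots of a probe were averaged. Each miRNA was represented by its probe with the highest mean over all 10 arrays, which 6 miRNAs with 1 probe left no choice of. Of 255 other detected probes of 242 miRNAs, 35 had a change of opposite sign in TP against control on floored values. None of these belonged to a miRNA past the threshold as scaled. The miRNAs past it on floored values only were not checked in this way. A probe was detected when at least 0.5 of its usable spots were well above background. The 328 miRNAs whose probe was detected on at least 2 arrays were tested. Between 39.4 and 49.7% of an array's spots were at or under 0, so an undetected miRNA can lie anywhere down to a floor of -28.14 on the log2 scale. Sizes of change on these as-scaled values are therefore not printed as folds. The same test was also run with values floored at the detection limit, the median over arrays of the lowest scaled signal of a spot well above background (0.0597, or -4.07 on the log2 scale). Counts are given from both, and log2 changes in the report are from the floored values, with the limma standard error (SE). A miRNA undetected on every array of a group has only a bound, written "at least N-fold". It sets the mean of the group where the miRNA was detected against the higher of each array's own detection limit and its signal. The bound is a difference of sample means without an SE, and the common floor or another scaling can give a smaller change.

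Comparisons used limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with data.table (version 1.17.8), and Benjamini-Hochberg adjustment over the 328 miRNAs at a threshold of 0.05. TP against control was fitted with 2 groups. Each collection time against control and the contrasts between times came from 1 fit of 4 group means. Lists of miRNAs with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera sets the members against the other tested miRNAs and fry sets them against no change. Their directions can therefore differ, and a camera direction of up can go with a negative mean change. The number of detected miRNAs was compared by an exact permutation test. The groups, tests, alternatives, lists and the rule for named miRNAs were fixed before the data were examined. That rule takes the 10 largest rises and falls past the threshold in TP against control, the 3 largest at each collection time, the miRNAs with the smallest p where fewer than 5 pass, up to 4 members per list, and always miR-146a-5p, miR-155-5p, miR-21-5p, miR-223-3p and miR-142-3p. It gave 72 tested miRNAs. Named outside it, after their values were seen, were miR-328-3p, miR-6089, miR-4459, miR-4516, miR-3135b, miR-1273g-3p, miR-197-3p, miR-6800-5p, miR-342-3p, miR-6869-5p, miR-99a-5p, miR-148a-3p and the miRNAs detected on a single array.

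On simulated data with 60 of the 328 miRNAs changed, TP against control recovered 3.25% of changes of log2 size 2, 23.5% of size 4 and 56.2% of size 8 on as-scaled values, and 77.8%, 96.8% and 100% on floored values. The share of false calls was 4.87% and 4.52%. For the collection times against control, in order, the recovery at size 4 was 1.5%, 2.25% and 5% as scaled, and 88.8%, 89.2% and 91.2% floored, and the share of false calls 3.2%, 4.52% and 7.18% as scaled and 5%, 5.82% and 4.76% floored, so 48 h as scaled and 24 h floored exceeded 5%. The simulated noise was normal with each miRNA's own spread, and the floor was not applied again. Simulated values could thus fall below the detection limit, and miRNAs at the floor had little spread. The recovery on floored values can therefore overstate that of the real test. The number of arrays limits the precision.

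Alternatives were a percentile over all probes, quantile scaling, no scaling, normexp background correction with an offset of 50 and quantile scaling, the software's total gene signal, the mean over all probes of a miRNA, the deposited value table, other filters on detection, trended and robust empirical Bayes, the replicate number or the slide as a block, the 2 groups compared alone, the average of the times, and leaving out each sample. The detection-limit floor was also among them. Slide 1 alone, slide 1 without the faintest 48 h array, the slide block on floored values, list tests on floored values or with the slide, and list directions with normexp and the total gene signal were added after the data were examined. Slide 1 held 8 of the arrays, and slide 2 held the other 2, Control replicate 1 and TP 48 h replicate 1. Probe positions are those in the files of slide 2, whose headers name build GRCh37 (hg19). They cover 90 of the 328 tested probes, and 238 have none.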

Results

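Exosomes were collected from the medium of macrophages made from THP-1, a human monocytic leukaemia line, by treatment with the phorbol ester PMA at 100 ng/ml. The macrophages had been exposed for 12 h to Treponema pallidum, the spirochaete that causes syphilis, at 30 bacteria per cell, or to buffer, and were then washed and kept in fresh medium without serum exosomes. The series asks which exosomal miRNAs differ after exposure to the bacterium. It holds 3 control arrays and 7 TP arrays, of which 2 were collected at 12 h, 2 at 24 h and 3 at 48 h.

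The number of detected miRNAs varied widely. It was 310, 113 and 150 in the controls, 106 and 180 at 12 h, 59 and 101 at 24 h, and 582, 37 and 233 at 48 h, of 2549 on the array. The mean was 191 ± 104.7 (SD, n = 3) in controls and 185.4 ± 187.5 (SD, n = 7) in TP samples, a difference of -5.57 that lay within the spread (exact permutation test, two-sided, p = 0.975; the smallest p that 120 splits allow is 0.00833). The direction of this difference turned when single arrays were left out, to 53.9 without Control replicate 1, 7.67 without TP 12 h replicate 1, 15.5 and 8.5 without TP 24 h replicates 1 and 2, and 19.2 without TP 48 h replicate 2. On slide 1 the means were 131.5 ± 26.16 (SD, n = 2) in controls and 119.3 ± 74.21 (SD, n = 6) in TP samples, and on slide 2 the single arrays held 310 and 582. The reference signal ran from 16.7 on TP 48 h replicate 2 to 772 on TP 48 h replicate 1. In all, 612 miRNAs were detected on at least 1 array and 23 on every array.

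**Figure D1:**
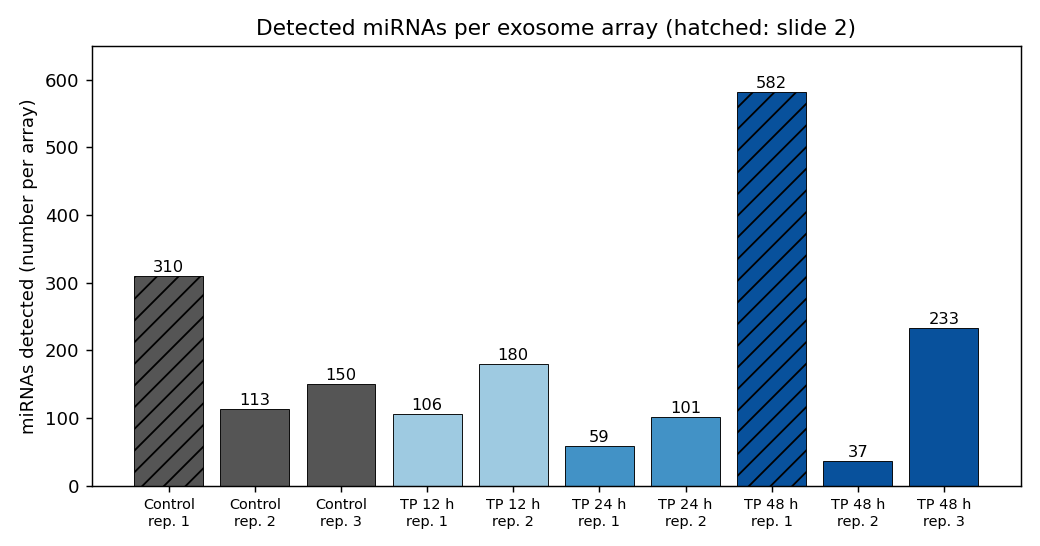
Number of miRNAs detected per exosome array (y axis, count; x axis, sample), with bars coloured by group and hatched for slide 2. The 48 h samples span 37 to 582, and the controls 113 to 310.

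Exposure to the bacterium was accompanied by more miR-145-5p in exosomes, which passed in 26 of 26 alternatives. miR-1290 and miR-6125 were lower and also passed both on as-scaled and on floored values, but in only 11 of 27 and 9 of 26 alternatives. miR-145-5p is a miRNA abundant in smooth muscle and fibroblasts (probe at chromosome 5, 148810230 to 148810246, GRCh37). It was detected in 6 of 7 TP samples and in 0 of 3 controls, with all 7 TP arrays above every control. It was at least 7.73-fold higher (adjusted p = 0.00148 as scaled, 0.0224 floored). Its log2 change was 2.81 floored and 1.24 with normexp and quantile scaling, both smaller than that bound. miR-1290, whose sequence overlaps U2 small nuclear RNA, was detected in all 10 samples and fell 14.7-fold, with a log2 change of -3.88 ± 0.67 (SE; adjusted p = 0.0382 as scaled, 0.0113 floored), and all 7 TP arrays lay below every control. miR-6125, a GC-rich entry of the array, changed by -2.80 ± 0.41 (SE; adjusted p = 0.0382 and 0.00558) and was detected in 3 of 7 TP samples and 3 of 3 controls. With the slide as a block the adjusted p on as-scaled values was 0.00237 for miR-145-5p, 0.0232 for miR-1290 and 0.0413 for miR-6125. Within slide 1 the floored log2 changes were 2.53, -4.51 and -2.31, and within slide 2, with 1 array each, 4.49, -2.95 and -3.88. The calls of miR-1290 and miR-6125 ended with no scaling (adjusted p = 0.329 and 0.382) and with the percentile over all probes (0.171 and 0.211), and that of miR-6125 also on slide 1 alone (0.133). The as-scaled log2 changes hardly moved under the first 2, at -3.85 and -3.90 for miR-1290 against -3.88, and -3.59 and -3.64 for miR-6125 against -3.68. With quantile scaling the changes of miR-1290 and miR-6125 were smaller, at -1.95 and -2.88 (adjusted p = 0.214 and 0.0619). With normexp they were -1.49 and -0.79 (0.0373 and 0.00618). Both calls ended without Control replicate 2 (0.153 for each), Control replicate 3 (0.172 and 0.0822), TP 12 h replicate 1 (0.0698 and 0.0695), TP 12 h replicate 2 (0.0723 for each), TP 24 h replicate 1 (0.064 for each), TP 24 h replicate 2 (0.0831 and 0.077) or TP 48 h replicate 3 (0.0583 and 0.0694), and that of miR-6125 without Control replicate 1 (0.146). Over all alternatives their adjusted p ran from 7.73e-05 to 0.732 and from 0.00558 to 0.771. The change stayed negative, from -4.59 to -1.49 and from -4.83 to -0.79.

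In TP against control, 19 of 328 miRNAs passed on as-scaled values, 14 higher and 5 lower, and 18 on floored values, 2 higher and 16 lower. Only 3 passed in both and 34 in either. Of the 19, 13 were undetected in every control and 11 were detected on under 0.5 of the arrays in each group. Among the 14 higher ones, miR-34a-5p, a p53 target, was at least 2.48-fold higher (4 of 7 TP samples against 0 of 3; adjusted p = 0.0164), and miR-328-3p at least 2.43-fold higher (6 of 7 against 0 of 3; adjusted p = 0.0382). On floored values both missed the threshold (adjusted p = 0.291 and 0.0659). miR-10b-5p was detected in 5 of 7 TP samples and 1 of 3 controls, with a log2 change of 1.30 ± 0.56 (SE; adjusted p = 0.0336 as scaled, 0.291 floored). miR-27b-3p was at least 1.04-fold higher (3 of 7 against 0 of 3; adjusted p = 0.0318). For the other 9 the signal was too near the detection limit for a fold. These were miR-143-3p, miR-34b-3p, miR-34c-5p, miR-449a and miR-363-3p (each 2 of 7 TP samples against 0 of 3 controls) and miR-509-5p, miR-378j, miR-199a-3p and miR-424-5p (each 3 of 7 against 0 of 3). Among the 5 lower ones, miR-3665 and miR-4530 were detected in 1 of 7 TP samples and 2 of 3 controls, and miR-575 in 1 of 7 and 1 of 3.

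Several miRNAs passed on floored values only. The erythroid miRNA miR-451a (chromosome 17, 27188404 to 27188424) was 9.71-fold higher, 3.28 ± 0.66 on the log2 scale (SE; adjusted p = 0.0627 as scaled, 0.0213 floored, 0.0479 as scaled with the slide block), and higher in 7 of 7 TP arrays. Within slide 1 its change was 3.30, and within slide 2 it was 4.02. miR-1246, which like miR-1290 overlaps U2 RNA, was 11.1-fold lower, -3.48 ± 0.63 (SE; adjusted p = 0.0505 as scaled, 0.0143 floored, 0.0438 as scaled with the slide block), and lower in 7 of 7. Over the alternatives miR-451a passed in 8 of 26 (log2 change 1.66 to 4.29, highest adjusted p = 0.818). miR-1246 passed in 8 of 27 (-4.02 to -1.05, highest adjusted p = 0.796). The tumour-suppressor miRNAs let-7b-5p and let-7c-5p had changes of -3.02 ± 0.62 and -2.58 ± 0.55 (SE; adjusted p = 0.0224 and 0.0236 floored, 0.0799 and 0.219 as scaled). Also lower were miR-23a-3p (-2.36 ± 0.44, SE), miR-2861 (-2.58 ± 0.44), miR-4516 (-2.96 ± 0.43), miR-6089 (-2.81 ± 0.59), miR-3135b (-3.19 ± 0.35), miR-1273g-3p (-2.69 ± 0.30), miR-197-3p (-1.35 ± 0.14) and miR-6800-5p (-1.81 ± 0.27), with adjusted p of 0.0236 or less floored and 0.0534 or more as scaled. The rest of the 16 were miR-6869-5p (-1.64 ± 0.38), miR-155-5p (-0.50 ± 0.09) and miR-30c-5p (-0.50 ± 0.11, SE), and each of these 16 was lower in 7 of 7 TP arrays. miR-155-5p was detected on only 3 arrays. Values held at the floor have little spread, so its SE and floored adjusted p can be too small. When the test was confined to the 21 miRNAs detected on all 10 arrays, 4 passed and all were lower: miR-1290, miR-1246, miR-6089 and miR-4459 (adjusted p = 7.73e-05, 0.000256, 0.00342 and 0.015). The detection-limit floor changes no value of these 4.

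**Figure D2:**
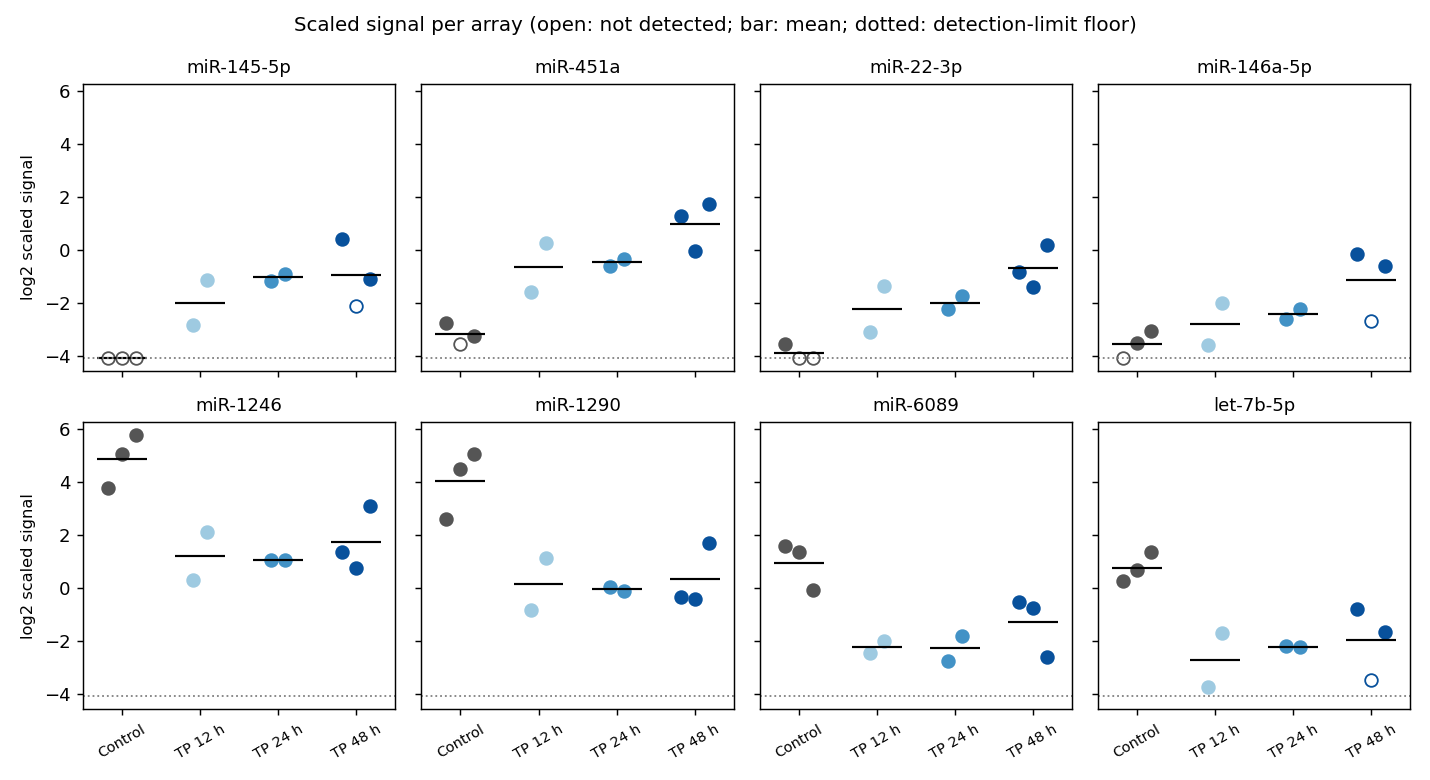
Scaled signal (y axis, log2, floored at the dotted line) of 8 miRNAs per array and group (x axis), with open points for arrays without detection and bars for group means. Every TP array lies above the 3 controls for miR-145-5p, miR-451a and miR-22-3p, and below them for miR-1246, miR-1290, miR-6089 and let-7b-5p.

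The innate immune miRNAs did not pass as a group. In the NF-kB and TLR-responsive list, 0 of 7 tested members passed on as-scaled values, also when adjusted over the list alone (camera adjusted p = 0.437). Its mean change was -0.67 as scaled, 0.16 with normexp and quantile scaling and 0.25 floored, and its median -1.83 as scaled and 0.00 floored. Camera gave the direction up, relative to all tested miRNAs, whose median change was -1.61 as scaled. Fry, which is relative to no change, gave down (adjusted p = 0.964). On floored values 1 member was lower, miR-155-5p, also over the list alone. miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, was detected in 6 of 7 TP samples and 2 of 3 controls with a change of 1.58 ± 0.71 (SE; adjusted p = 0.242 as scaled, 0.301 floored). Its change was 1.01 within slide 1 and 3.92 within slide 2. miR-155-5p, which is induced in activated macrophages, was detected in 1 of 7 TP samples and 2 of 3 controls (-0.50 ± 0.09, SE, with adjusted p = 0.128 as scaled and 0.0149 floored). Values held at the floor have little spread, so this SE and the floored adjusted p can be too small. miR-21-5p was detected in all 10 samples (1.29 ± 0.90, SE; adjusted p = 0.49), and the myeloid miR-223-3p in 6 of 7 and 3 of 3 (1.65 ± 0.69, SE; adjusted p = 0.345). miR-142-3p was detected on 1 array and was not tested. In the monocyte and macrophage list, 2 of 9 tested members were higher (miR-34a-5p and miR-424-5p), and 3 higher and 1 lower when adjusted over the list alone. That list passed with the preset correlation (adjusted p = 0.0141) and not on floored values (adjusted p = 0.139), and its adjusted p = 0.773 with an estimated correlation. miR-22-3p of this list was detected in 7 of 7 TP samples and 1 of 3 controls (2.40 ± 0.60, SE; adjusted p = 0.0534 as scaled, 0.0531 floored, 0.0232 as scaled with the slide block).

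Lists of other tissues moved furthest on as-scaled values. In the mesenchymal list 4 of 5 tested members were higher, and 5 when adjusted over the list alone (camera adjusted p = 5.84e-09, and adjusted p = 0.00846 with an estimated correlation). The members were miR-145-5p, miR-143-3p, miR-10b-5p and miR-199a-3p. On floored values 1 member passed, and the list gave adjusted p = 0.0122 with the preset and adjusted p = 0.747 with an estimated correlation. In the testis and germ cell list 4 of 5 tested members were higher, miR-34b-3p, miR-34c-5p, miR-449a and miR-509-5p, and 5 when adjusted over the list alone (adjusted p = 5.84e-09, and adjusted p = 0.0311 with an estimated correlation). None passed on floored values, where the list gave adjusted p = 0.139. The floored mean changes on slides 1 and 2 were 0.83 and 2.18 for the mesenchymal and 0.12 and 1.01 for the testis list, so both were larger on the slide that holds the brightest array. Their mean change was positive under the 6 scalings, in the deposited value table and with the floor. With the floor both control means lay at -4.07 (SD 0), so that change could not be negative. Apart from miR-10b-5p, the members named above as higher met the detection filter through TP arrays alone, so the shared sign adds little. Muscle and lymphocyte, endothelial and liver lists had 1 tested member each (miR-133b and miR-126-3p), the neuronal list 2 (miR-124-3p and miR-128-3p), the red blood cell list 2 (miR-451a and miR-486-5p), the hypoxia and p53 list 2 (miR-34a-5p and miR-210-3p), the miR-181 list 1 (miR-181b-5p) and the epithelial list 0. Of these, miR-34a-5p passed on as-scaled values and miR-451a on floored values. Adjusted over the list alone, miR-451a and miR-34a-5p were higher as scaled. miR-181b-5p was lower as scaled at an unadjusted p under 0.05 (limma), since a list with 1 tested member leaves nothing to adjust over. Its floored change was -0.04, with means at or near the floor in TP samples (-4.06) and controls (-4.03), so no fall can be read.

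GC-rich entries and the let-7 family were the lists that passed on the lower side, the let-7 family on floored values only. Of 22 tested GC-rich entries, 2 fell on as-scaled values (miR-6125 and miR-3665) and 7 were lower when adjusted over the list alone. On floored values 5 were lower, and 8 over the list alone. The list passed with the preset correlation (adjusted p = 0.0182 as scaled, 0.000669 floored), with adjusted p = 0.773 and adjusted p = 0.747 with an estimated correlation. Its floored mean change was -1.14 within slide 1 and -0.16 within slide 2. Of 8 tested let-7 members none passed on as-scaled values (camera adjusted p = 0.151) and 2 were lower on floored values, 3 over the list alone (adjusted p = 0.0307, and adjusted p = 0.747 with an estimated correlation). All 8 had negative changes under each of 6 scalings and in the deposited value table, and 7 on floored values. Its changes within slides 1 and 2 were -1.08 and -0.50. The entries that overlap other small RNAs held 9 tested members, of which miR-1290 fell, and 2 were lower over the list alone. Their floored mean was -0.39, their median 0.60 and the test's direction up (adjusted p = 0.437), with miR-1260a at 1.71 ± 0.58 and miR-4286 at 0.60 ± 0.30 (SE; adjusted p = 0.279 and 0.242). The other lists missed the threshold: miR-17-92 clusters (1 of 10 higher, miR-363-3p; adjusted p = 0.906), miR-23/27/24 (1 of 5 higher, miR-27b-3p, and 1 higher and 1 lower over the list alone; 0.204), miR-15/16 (0 of 5, and 1 higher over the list alone; 0.437, floored mean -0.31, median 0.01 and direction up), miR-29 (0 of 3; 0.151), miR-30 (0 of 5; 0.921, direction up as scaled and down floored) and miR-320 (0 of 5; 0.539). Of these, the miR-17-92 and miR-320 lists also had the direction down, with floored means of -0.62 and -0.42 and 9 of 10 and 5 of 5 members negative as scaled.

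**Figure D3:**
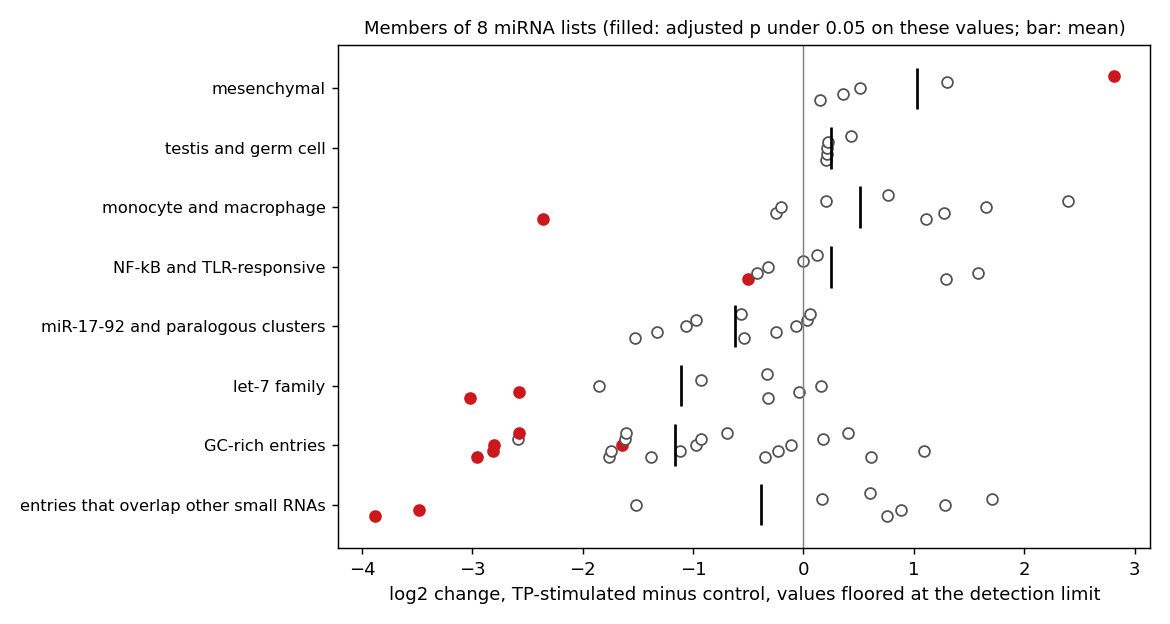
Log2 change of TP against control on floored values (x axis) for the tested members of 8 lists (y axis), 1 point per miRNA, filled where the adjusted p on these values is under 0.05, with the list mean as a bar. Points of the GC-rich and let-7 lists lie mostly below 0, with means of -1.16 and -1.11, and the mesenchymal mean is 1.02.

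The count of 19 depended on scaling and on single arrays. It was 4 (4 higher, 0 lower) with no scaling or with the percentile over all probes, and the median change over all tested miRNAs was -1.61 as scaled, -1.43 unscaled, -0.98 with quantile scaling and 0 floored, so as-scaled changes are relative to that shift. The slide block gave 23 (17 higher, 6 lower) and slide 1 alone 16 (12 higher, 4 lower). Leaving out 1 array gave 5 without Control replicate 3, 6 without Control replicate 2, TP 12 h replicate 2 or TP 48 h replicate 3, 7 without TP 24 h replicate 2, 8 without TP 12 h replicate 1, 29 without TP 48 h replicate 2 and 37 without TP 48 h replicate 1, with 14 higher and 23 lower in the last.

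At 12 h after washing, no miRNA passed in limma on either kind of value (38 at an unadjusted p under 0.05 as scaled, 29 floored). miR-145-5p was detected in 2 of 2 samples and 0 of 3 controls and was at least 4.69-fold higher, but missed the threshold (adjusted p = 0.0714). The smallest adjusted p, 0.0602, was that of miR-143-3p, miR-509-5p and miR-125b-2-3p, followed by miR-34b-3p (0.0624), all at or near the detection limit. Among the 21 miRNAs detected on all arrays, 4 were lower: miR-1290 (15-fold; adjusted p = 0.0161), miR-1246 (12.6-fold; 0.0165), miR-4459 (11.4-fold; 0.0169) and miR-6089 (9.15-fold; 0.0292). With the slide block miR-4459 no longer passed (adjusted p = 0.0689) and the other 3 did (miR-6089 0.0443). Of 13 lists, 5 passed with the preset correlation and 2 with an estimated one: mesenchymal (adjusted p = 0.0257 estimated) and testis (adjusted p = 0.0353 estimated) upwards. On floored values neither passed with an estimated correlation (adjusted p = 0.529 for both), and the testis list, with a mean change of 0.01 and a median of 0.00, did not pass with the preset either (adjusted p = 0.226). GC-rich and let-7 entries passed floored with the preset (0.000211 and 0.0143) and not with an estimated correlation (0.529 for both). GC-rich and let-7 entries downwards and the monocyte list upwards passed with the preset only, each with adjusted p = 0.786 estimated. The count of 0 became 3 with the slide block, 6 without Control replicate 1, 6 with quantile scaling and 7 without TP 48 h replicate 2.

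At 24 h, 13 miRNAs passed on as-scaled values, 4 higher and 9 lower, and 4 others, all lower, on floored values. miR-145-5p was at least 9.06-fold higher (2 of 2 samples against 0 of 3; adjusted p = 0.0393 as scaled, 0.12 floored). The other 3 higher ones, miR-143-3p, miR-509-5p and miR-34b-3p, were detected on no array of either group. Of the 9 lower ones, miR-6869-5p was at least 2.08-fold lower, miR-638 at least 2.07-fold and miR-619-5p at least 1.44-fold, each in 0 of 2 samples against 3 of 3 controls (adjusted p = 0.0474, 0.0346 and 0.0393). miR-155-5p was detected in 0 of 2 and 2 of 3 (adjusted p = 0.0393) and miR-342-3p in 0 of 2 and 3 of 3 (0.0423). The remaining 4, miR-6865-5p, miR-4465, miR-328-5p and miR-125b-2-3p, were detected in 0 of 2 and 1 of 3. On floored values miR-3135b was at least 5.86-fold, miR-23a-3p at least 5.31-fold, miR-1273g-3p at least 4.17-fold and miR-197-3p at least 1.69-fold lower (adjusted p = 0.0477, 0.047, 0.0477 and 0.047). miR-8089, miR-7704, miR-378j, miR-4634 and miR-3665 came next as scaled and did not pass (adjusted p = 0.0517 to 0.0676). Among the 21 miRNAs detected on all arrays, the same 4 as at 12 h were lower. These were miR-1290 (17-fold, adjusted p = 0.00924), miR-1246 (14-fold, 0.0106), miR-4459 (10.2-fold, 0.0253) and miR-6089 (9.51-fold, 0.0253). With the slide block miR-4459 no longer passed (0.104). Of 13 lists 3 passed with the preset correlation, mesenchymal, testis and GC-rich, with adjusted p = 0.0636, adjusted p = 0.0988 and adjusted p = 0.887 with an estimated correlation. On floored values the testis list missed the threshold (mean change 0.02; adjusted p = 0.457), and the mesenchymal list passed with the preset (0.0369) but not with an estimated correlation (0.557), as did GC-rich (0.000206) and let-7 entries (0.0184) downwards, each at 0.557 estimated. The 13 calls became 0 with no scaling, the percentile over all probes, normexp, the total gene signal or no filter, and 49 with the 2 groups alone (6 higher, 43 lower). They also became 0 without Control replicate 2, TP 24 h replicate 1, TP 24 h replicate 2 or TP 48 h replicate 3, 1 without Control replicate 3, 3 without TP 12 h replicate 1 or 2, 8 without Control replicate 1 (7 higher, 1 lower), 20 without TP 48 h replicate 1 (5 higher, 15 lower) and 44 without TP 48 h replicate 2 (7 higher, 37 lower), while the slide block gave 11 (5 higher, 6 lower) and slide 1 alone 12 (7 higher, 5 lower).

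At 48 h, 6 miRNAs passed on as-scaled values, all higher, and 8 others on floored values, 5 higher and 3 lower. miR-145-5p was at least 9.71-fold higher (2 of 3 samples against 0 of 3; adjusted p = 0.0176 as scaled, 0.0708 floored). miR-143-3p, miR-34b-3p, miR-363-3p, miR-509-5p and miR-449a also rose, each detected in 2 of 3 samples and 0 of 3 controls (adjusted p = 0.0157 to 0.0176). On floored values miR-451a was 18-fold higher (4.17 ± 0.61, SE; adjusted p = 0.0203) and miR-22-3p 9.31-fold higher (3.22 ± 0.55, SE; 0.0291), with 0.72 ± 0.12 for miR-99a-5p, 1.47 ± 0.24 for miR-29c-3p and 0.91 ± 0.12 for miR-148a-3p. The 3 lower ones were miR-3135b, miR-1273g-3p and miR-197-3p, at -3.19 ± 0.48, -2.66 ± 0.40 and -1.29 ± 0.18 (SE; each adjusted p = 0.0203). miR-34a-5p, at least 4.26-fold higher, and miR-34c-5p did not pass (both adjusted p = 0.0588), nor did miR-497-5p, miR-424-5p and miR-378j. Among the 21 miRNAs detected on all arrays, 2 were lower, miR-1290 (13.2-fold, adjusted p = 0.00735) and miR-1246 (8.79-fold, 0.0254). Both also passed with the slide block (0.000901 and 0.00516). Of 13 lists, 3 passed with the preset correlation and 2 with an estimated one, mesenchymal and testis upwards (both adjusted p = 0.0358 estimated). On floored values both passed with the preset (adjusted p = 0.00578 and 0.0174), but not with an estimated correlation (0.601 for both) or fry (0.082 for both). GC-rich entries downwards (0.00578) and the miR-29 family upwards (0.0382) also passed floored with the preset and not with an estimated correlation (0.65 and 0.559), and the miR-29 family was the 1 list to pass fry floored (0.0152). The monocyte list gave adjusted p = 0.00737 and adjusted p = 0.678 with an estimated correlation. The 6 calls became 0 with no scaling, the percentile over all probes, the total gene signal or no filter, 10 with quantile scaling or the mean over probes, and 7 (2 higher, 5 lower) with normexp. They became 0 without Control replicate 2 or TP 48 h replicate 3, 3 without Control replicate 3, 10 without TP 48 h replicate 2 and 12 without Control replicate 1, while the slide block gave 7 and slide 1 alone 6.

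Between collection times no miRNA passed in limma. The counts at an unadjusted p under 0.05 were 8 for 24 h against 12 h, 2 for 48 h against 12 h and 20 for 48 h against 24 h as scaled, and 1, 16 and 19 floored. The test of any difference between the 3 times passed 0 miRNAs (11 unadjusted as scaled, 13 floored). miR-145-5p differed by 0.95 ± 0.83 between 24 h and 12 h and by 0.10 ± 0.76 between 48 h and 24 h on floored values (SE; adjusted p = 1 in both). miR-451a differed by 1.65 ± 0.68 and miR-22-3p by 1.55 ± 0.62 between 48 h and 12 h (SE; adjusted p = 0.711 in both, floored). The smallest adjusted p between times as scaled was 0.0806, for miR-6865-5p between 48 h and 24 h, which was detected in 1 of 3 and 0 of 2 samples. miR-363-3p, miR-4465, miR-638 and miR-8089 followed (adjusted p = 0.408). For 24 h against 12 h, miR-4465, miR-6865-5p, miR-328-5p, miR-619-5p and miR-638 had the smallest p, and all were undetected at both times. For 48 h against 12 h these were miR-125b-2-3p, miR-8089, miR-6865-5p, miR-378i and miR-4299 (adjusted p = 0.6 to 0.999). Without TP 48 h replicate 2 the counts were 16 for 48 h against 24 h and 1 for 24 h against 12 h and for the test over all times. Without TP 12 h replicate 1 or 2, 1 miRNA passed for 48 h against 24 h, as with quantile scaling.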

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

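All tests weighed here were chosen after the results they explain were seen, except the blood and serum miRNAs for miR-451a and the other splits of the samples, which were set down before. For the RNA carried over with bacteria, a condition on collection time was added after a first look at its value, and under the first wording that explanation would have met its prediction. For the GC-rich entries, the tests of the slide and of dimmer arrays were replaced after first counts that decided nothing (5 of 6 and 1 of 2 arrays) were seen. The test of dimmer arrays was also replaced for miR-1246 and miR-1290, where the first count (2 of 2) had already met the prediction against that cause. The condition that makes a blood and serum miRNA usable was also added after its result was seen.

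TP 48 h replicate 1 stands apart from the other TP samples and was the only TP array on slide 2. The only control on slide 2, Control replicate 1, was also the brightest control (reference signal 250.1, with 310 detected miRNAs). Sample and slide can therefore not be told apart here. TP 48 h replicate 1 held 582 detected miRNAs against 233 in the next (gap over range 0.64, above the critical value of Dixon's test for 7 samples). Its reference signal was 772 against 271 (0.663). Of 21 groups of values checked, chance is expected to mark about 1 in 20. On that array, 250 miRNAs were detected that no other array detected, against 22 for Control replicate 1, and they lie outside the tested set. The brightest of them were miR-150-5p, miR-4698 and miR-711 (unscaled log2 signal 8.49, 8.14 and 7.66).

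miR-145-5p and other mesenchymal and testis miRNAs were higher in TP samples. For miR-145-5p, a slide difference is argued against by slide 1 alone (6 of 6 TP arrays above both controls, mean difference 2.53), and brighter TP arrays by 2 of the 3 TP arrays dimmer than any control detecting it while 0 controls did. Both counts follow from the detection and ranks of miR-145-5p given in the results, so they are no independent test. Of the other 7 calls in these lists, 0 passed on floored values, so the order of values under the detection limit may account for them. RNA carried over with bacteria grown in testis tissue, a source the labels do not state, stays open: the testis members changed by 0.25 (SE over members 0.04) and the mesenchymal by 1.02 (SE 0.49), and the testis members were higher at 48 h than at 12 h by 0.56 (SE 0.09), but their mean lay at or near the floor of -4.07 on every 12 h and 24 h array (-4.07 to -4.03), where no change can be read. A response of the macrophages to the bacterium stays open as a hypothesis.

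GC-rich entries, and miR-1246 and miR-1290, were lower in TP samples. A trend of the change with probe GC content missed its prediction as the whole cause: a mean of -0.77 (SE over 22 members 0.25) was left after its removal, against -1.16 before. For the slide, the GC-rich mean was -1.14 within slide 1 (SE over members 0.23, with 2 controls there) and -0.16 within slide 2. Camera with the preset correlation gave adjusted p = 0.0336 with the slide block and 0.0149 on slide 1 alone. The members share the arrays (estimated correlation 0.442 as scaled), so these SEs and p-values can be too small. Neither the GC trend nor the slide is settled for the list. For miR-1246 and miR-1290 a slide difference is argued against by 6 of 6 arrays of slide 1 (mean difference -4.26), which follows from all 7 TP arrays lying below every control. Dimmer TP arrays stay open for the GC-rich entries. The 3 TP arrays of slide 1 brighter than its 2 controls lay below both. Over both slides, however, only 1 of the 2 TP arrays brighter than every control lay below all controls. For miR-1246 and miR-1290 dimmer arrays are argued against by 3 of 3 on slide 1 and 2 of 2 over both slides. The GC-rich call itself ended with an estimated correlation (0.773) and without Control replicate 2 (0.0823) or TP 48 h replicate 3 (0.0585). What stays open, for the GC-rich entries beside the causes above, is a response to the bacterium, as a hypothesis, or a technical cause not tested here, such as RNA isolation.

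miR-451a, a miRNA of red blood cells, was higher in 7 of 7 TP samples. A slide difference is argued against by 6 of 6 TP arrays of slide 1 above both controls (3.30), a count that follows from 7 of 7 being higher. More blood or serum RNA in the TP preparations stays open. The other 4 blood and serum miRNAs had a median change of -0.57 (spread 0.79), which met the bound set down against it, but that bound was wrong: miR-486-5p (0.00) lay at the floor, and miR-16-5p (-1.29) and miR-92a-3p (-1.06) were detected in 3 of 3 controls, a baseline that can hide a small share, which leaves 1 usable miRNA, miR-25-3p (-0.07). A response of the macrophages stays open as a hypothesis, as does a technical cause not tested here.

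For TP against control, 3 of 100 splits of the 10 arrays, the real one included, gave as many as 19 miRNAs past the threshold on as-scaled values. That share is under 0.05, but the splits ignored the slides and were not run on floored values. The count also depends on scaling and single arrays, so chance is not excluded. The highest other split gave 39. It set TP 12 h replicate 1, TP 24 h replicate 1 and TP 48 h replicate 2 against the rest. Each of these had the fewest detected miRNAs (106, 59 and 37) and the lowest reference signal of its collection time. Whether this faintness accounts for the 39 was not tested. For TP 48 h against control the 10 splits are too few for a share under 0.05; 2 gave as many as the real 6, and the highest other gave 7.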

How the results depend on the processing

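Slide 1 alone, slide 1 without the faintest 48 h array (TP 48 h replicate 2), the slide block on floored values and the list tests on floored values or with the slide were chosen after the results were seen. The cause of the changes below was not tested, except that fewer miRNAs are tested when detection on all 10 arrays is asked for.

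For TP against control the 19 miRNAs past the threshold (14 higher, 5 lower) became 4 with the percentile over all probes, no scaling or no filter (each 4 higher, 0 lower), 4 with detection on all 10 arrays (0 higher, 4 lower), 30 with normexp and quantile scaling (7 higher, 23 lower), 12 with the total gene signal (4 higher, 8 lower), 11 with the mean over probes or the replicate block (each 8 higher, 3 lower), 29 on slide 1 without the faintest array (18 higher, 11 lower), and 10 with the average of the times (8 higher, 2 lower). Quantile scaling gave 24 (19 higher, 5 lower), trended and robust empirical Bayes 22 (14 higher, 8 lower), the deposited values 22 (7 higher, 15 lower), the floor 18 (2 higher, 16 lower), the slide block 23 (17 higher, 6 lower), slide 1 alone 16 (12 higher, 4 lower) and the slide block on floored values 27 (5 higher, 22 lower). Most calls were thus lower, not higher, with normexp, the total gene signal, detection on all 10 arrays, the deposited values and both floored settings, and without TP 48 h replicate 1 (14 higher, 23 lower). Leaving out 1 sample gave 5 to 37. As scaled, 2 of 13 pairs with the same replicate number correlated above 0.1 (median -0.139), against 10 of 24 with different numbers (median 0.049). On floored values these were 6 of 13 (median 0.094) and 7 of 24 (median -0.0915). In a group of 2 the deviations from the group mean mirror each other, so these pairs are not independent. Pairing by replicate number is therefore not settled on either kind of value.

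For 12 h the count of 0 (limma; 38 unadjusted) became 6 with quantile scaling, 1 with the mean over probes or the deposited value table, 4 with detection on all 10 arrays, 3 with the slide block or slide 1 alone and 9 on slide 1 without the faintest array; leaving out 1 sample gave 0 to 7. For 24 h the 13 became 0 with the percentile over all probes, no scaling, normexp, the total gene signal or no filter, 4 with the floor, detection on all 10 arrays or trended and robust empirical Bayes, 1 with the replicate block, 2 with the slide block on floored values, 29 on slide 1 without the faintest array and 49 with the 2 groups alone, and 0 to 44 without 1 sample. For 48 h the 6 became 0 with the percentile over all probes, no scaling, the total gene signal, no filter or the replicate block, 10 with quantile scaling or the mean over probes, 3 with the deposited value table and 2 with detection on all 10 arrays (0 higher, 2 lower), and 0 to 12 without 1 sample. Normexp gave 7, most of them lower (2 higher, 5 lower). Between times the count stayed 0 except 1 with quantile scaling for 48 h against 24 h. Leaving out 1 sample gave 0 to 1 for 24 h against 12 h, 0 to 0 for 48 h against 12 h, 0 to 16 for 48 h against 24 h and 0 to 1 over all times.

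The 4 lists of TP against control became 2 with an estimated correlation or fry and 0 with an estimated correlation on floored values, and 3 to 5 without 1 sample. The difference in detected miRNAs ran from -71.7 without TP 48 h replicate 1 to 53.9 without Control replicate 1.

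Among the named miRNAs and the lists, 1602 results under an alternative kept direction and side of the threshold, 255 lost the threshold, 78 passed it newly and 49 turned. miR-145-5p passed in 26 of 26 alternatives (adjusted p between 7.81e-05 and 0.0289), miR-1290 in 11 of 27 (7.73e-05 to 0.732) and miR-6125 in 9 of 26 (0.00558 to 0.771). miR-146a-5p, miR-21-5p and miR-223-3p passed in none.

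These turned, none of them past the threshold (log2 change). With the floor: miR-6865-5p 0.21, miR-125b-2-3p 0.02, miR-8089 0.03, miR-4634 0.00, miR-4465 0.02, miR-378i 0.01, miR-30a-5p -0.40, miR-30b-5p 0.13, miR-320a 0.06, miR-486-5p 0.00 and miR-126-3p 0.04. With the slide block on floored values: miR-6865-5p 0.36, miR-125b-2-3p 0.01, miR-8089 0.03, miR-4465 0.02, miR-378i 0.00, miR-30a-5p -0.13, miR-30b-5p 0.17, miR-320a 0.07, miR-486-5p 0.00 and miR-126-3p 0.03. With the total gene signal: miR-378i 1.10, miR-24-3p -0.04, miR-30a-5p -0.18, miR-30b-5p 0.11, miR-320a 0.45 and miR-126-3p 1.00. In the deposited value table: miR-29b-3p -0.10, miR-30a-5p -0.01 and miR-126-3p 0.60. With normexp: miR-30b-5p 0.03, miR-320a 0.02, miR-126-3p 0.04 and miR-124-3p 0.05. miR-126-3p also turned with the percentile over all probes (0.16), no scaling (0.33), the mean over probes (1.90), the replicate block (0.34) and the slide block (0.42), and without 1 sample in 5 of the 10 cases (0.18, 0.55, 0.66, 0.69 and 1.18; lowest -1.08). Leaving out 1 sample gave -1.74 to 2.73 for miR-29b-3p and -0.36 to 8.63 for miR-30a-5p, each turning without Control replicate 2, and -3.12 to 0.31 for miR-486-5p, turning without Control replicate 1, and miR-486-5p on slide 1 without the faintest array (0.90). The NF-kB list is counted as turned under fry (adjusted p = 0.964), which is relative to no change and not to the other miRNAs.

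Signal over background limits these results: between 37 and 582 miRNAs were detected per array, and 13 of the 19 calls had none detected in controls.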

Other observations

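The arrays of 1 collection time differed in likeness. Correlations across miRNAs were 0.71 to 0.88 between controls, 0.89 between the 12 h samples, 0.94 between the 24 h samples and 0.33 to 0.55 between the 48 h samples.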
